A study of Mus musculus with 2 samples.

How the data were processed

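Single-cell mRNA libraries were made on the inDrops droplet platform, which tags each captured transcript with a barcode for its droplet and a unique molecular identifier (UMI), per the labels' protocols. Lineage-depleted mouse bone marrow was the source. Cells sorted for live GFP signal alone came from mice with GFP at the Mds1 part of the Mecom locus together with Flt3-Cre, and they were mixed with wild-type long-term hematopoietic stem cells (LT-HSCs) sorted by the SLAM markers, per the labels. The reporter cassette lies between loxP sites, per the labels, so a cell in which Flt3-Cre has acted would lose it. 2 aliquots of this 1 pool were sequenced as separate libraries, called aliquot 1 and aliquot 2 here. The unit of replication is the pool, so n = 1, and the aliquots are technical.

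The deposited files hold raw UMI counts, whole numbers for 28206 features per droplet barcode, with no normalization by the authors. The submitters' processing notes name Bowtie 1.1.1, SAMtools 1.3.1 and RSEM 1.3.0 and the mouse build GRCm38, without their roles or settings. Reporter transcripts were counted by the authors against the cassette sequence, per the labels, and form a feature named GFP. Bowtie and RSEM can divide reads among near-identical copies, and how that was done is not given in the sources used here, so values of genes with many pseudogene copies, such as ribosomal protein genes, and of the repeated gene Erdr1 are uncertain. Of the feature symbols, 26589 were found in the gene table used for names. Xist and the immunoglobulin constant genes of the marker lists had no feature of that name. Gene positions were read from GENCODE vM21, an annotation of GRCm38.

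From these counts, barcodes with at least 500 UMIs and at most 20% mitochondrially encoded UMIs were kept as cells, with the reporter feature left out of all totals. Aliquot 1 held 2147 barcodes and 1801787 UMIs, of which 1574 barcodes were kept with a median of 946.5 UMIs. Aliquot 2 held 8662 barcodes and 4726601 UMIs, of which 1828 were kept with a median of 2071.5 UMIs. The barcode numbers equal the cell numbers stated in the labels. The filter the authors used to reach their stated number of GFP cells is not given in the sources used here. Doublets were not removed in the main results. Scrublet, run per aliquot in scanpy with an expected rate of 6%, marked 11 cells in each aliquot, 0.699% and 0.602%, and none of them held a reporter UMI.

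Reporter cells were kept cells with at least 1 reporter UMI, and all other kept cells formed the comparison. A cell without a reporter UMI may still have come from the GFP sort, because detection of 1 transcript species is incomplete at this depth. Counts were summed over each cell set and given as CPM, counts scaled to a total of 1e6, with exact Poisson intervals. The ratio of CPM has an exact conditional binomial interval, and shares of cells have exact Clopper-Pearson intervals, all at 95%. These intervals cover counting error only, since UMIs of a gene come in bursts from single cells and cells are not replicates. No test between groups was possible and no p-value is given. A count of 0 was bounded by 3 counts over the cell set.

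Each of 15 gene lists was summarised by the median log2 ratio of members with at least 10 UMIs observed or expected in the smaller cell set. That median was placed among 10000 random lists of the same size drawn within 20 bins of expression. Mecom was also used to split cells, after thinning each cell to 500 UMIs, with Mecom itself left out. Clustering used scanpy 1.11.5 on log-normalised counts (10000 per cell), 2000 variable genes, 30 principal components, 15 neighbours and Leiden resolution 1.0 (leidenalg 0.10.2), without the reporter. A cluster took the name of the marker list, of 12, with most members at least 2-fold above all other cells with at least 10 UMIs, given at least 3 such members and no tie. Other software was Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9.

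Genes were named by a rule set before the data were examined, as were the lists, the markers and most alternatives. It takes members of the LT-HSC, multipotent progenitor (MPP) and sex-linked lists with at least 10 UMIs. It adds the 10 highest and 10 lowest ratios among genes with at least 20 UMIs observed or expected in the smaller set, seen or expected in at least 5 of its cells and with 1 direction in both aliquots (an aliquot counting from 5 UMIs). It also allows the 4 members with most UMIs of any other list. 3440 genes reached 10 UMIs and 1015 could be ranked. Genes named outside the rule are marked as chosen after their values were seen.

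The ratio calculation was tested on simulated counts for reporter against other cells, with 200 genes changed. The intervals held the simulated ratio for 95.8% of 947 unchanged genes, for 94.0% of 50 genes raised 2-fold and for 96.0% of 50 genes lowered to 0.5. Simulated counts had no bursts, so this is the best case. Alternatives changed the UMI minimum, the mitochondrial limit, the aliquots used, doublets, the reporter threshold, the averaging, the gene minimum, the comparison cells, the thinning and the clustering. Alternatives added after seeing the data were a Mantel-Haenszel ratio over aliquots, removal of the top cell per gene, of barcodes named in both aliquots, of the cycling and granulocyte classes or (in the Mecom split) of the granulocyte class, other draws of the thinning, and clustering without the genes that differed between the cell sets.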

Results

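The pool held rare GFP+ bone marrow cells from reporter mice among wild-type SLAM LT-HSCs, which per the series design were added to secure library quality. The transcriptome of the GFP+ cells was the object of the study. The 3402 kept cells carried 5668067 UMIs, 1640734 in aliquot 1 and 4027333 in aliquot 2. Kept cells of aliquot 2 were deeper, with a median of 1073 genes detected against 650.5 in aliquot 1. There is 1 pool and no biological replicate for any value below.

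Reporter transcripts were found in 71 of 3402 kept cells, 2.09% (95% interval 1.63 to 2.63%, Clopper-Pearson). Aliquot 1 had 23 such cells of 1574, 1.46% (0.929 to 2.19%), and aliquot 2 had 48 of 1828, 2.63% (1.94 to 3.47%). Of the 71 cells, 41 had 1 reporter UMI and 30 had 2 or more, up to 5. The labels state 46 GFP cells after the authors' processing, out of 2147 and 8662 barcodes before it, a count from another filter. Reporter cells had a median of 1702 UMIs and other cells 1412, with 927 against 947 in aliquot 1 and 2159 against 2069 in aliquot 2. In the 69 cells of the granulocyte-marker clusters, at a median of 1988 UMIs, no reporter UMI was found (a share of 0, up to 5.21% by counting error, of cells with a detected reporter UMI).

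Reporter cells differed from the other cells in single genes on both sides. Sort, mouse line and cell source go together in this pool, so none of the ratios below can be assigned to any of them alone. Cd34, a sialomucin that is low on mouse LT-HSCs and present on downstream progenitors, was at 0.291 times the level of other cells (0.145 to 0.523), and Plac8, a gene of myeloid and lymphoid progenitors, at 0.177 times (0.0763 to 0.349). Kit, the stem cell factor receptor used to sort the wild-type cells, was at 0.575 times (0.431 to 0.751), with 0.599 in aliquot 1 and 0.574 in aliquot 2. Mycn, a MYC family transcription factor, was at 3.27 times (2.65 to 4.00), with 103 UMIs in 38 of the 71 cells and ratios of 3.08 and 3.53 in the aliquots. Mecom, the gene that carries the reporter, was at 1.32 times (0.843 to 1.99), an interval that includes 1, from 24 UMIs.

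In CPM, Mycn stood at 752 (614 to 912) in reporter cells and 230 (217 to 243) in other cells. Kit stood at 394 (296 to 514) against 686 (664 to 708), Cd34 at 80.3 (40.1 to 144) against 276 (262 to 290) and Plac8 at 58.4 (25.2 to 115) against 330 (315 to 345). Mecom was at 175 CPM (112 to 261) against 132 (123 to 142). On GRCm38, Mecom spans chromosome 3 from 29951296 to 30548008 on the minus strand and Kit chromosome 5 from 75574916 to 75656722 on the plus strand. Cd34 lies on chromosome 1 from 194938819 to 194961279, Mycn on chromosome 12 from 12936093 to 12941914 and Plac8 on chromosome 5 from 100553725 to 100572245, all as protein-coding genes.

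**Figure D1:**
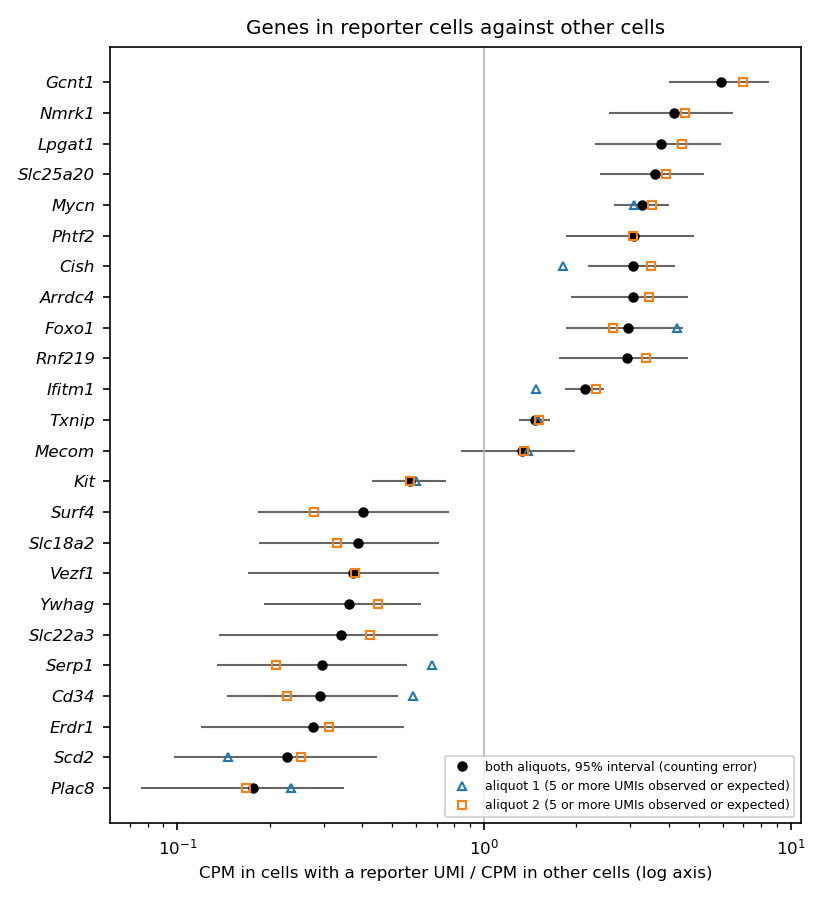
CPM in cells with a reporter UMI divided by CPM in other cells (log axis) for the 10 highest and 10 lowest ranked genes and for Kit, Mecom, Ifitm1 and Txnip; black points with lines are both aliquots with 95% intervals for counting error, and open symbols are single aliquots with at least 5 UMIs observed or expected, not drawn at 0. Txnip, Mecom, Kit and Mycn lie at similar ratios in both aliquots, and most UMIs of reporter cells come from aliquot 2.

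Among the other 9 of the highest ratios were Cish, a feedback inhibitor of cytokine signalling, at 3.06 times (2.18 to 4.19) in 23 cells, and Foxo1, a forkhead transcription factor, at 2.94 times (1.85 to 4.45) in 17 cells. Nmrk1, a nicotinamide riboside kinase, was at 4.17 times (2.56 to 6.48) and Arrdc4, an arrestin family gene, at 3.05 times (1.92 to 4.62). Lpgat1, Phtf2 and Rnf219 were at 3.78, 3.07 and 2.93 times, or 2.43, 1.75 and 1.97 without the cell holding most of their UMIs. Gcnt1, at 5.92 times, and Slc25a20, at 3.59 times, each rested on 1 cell: 25 of 34 Gcnt1 UMIs and 20 of 30 Slc25a20 UMIs came from a single cell, without which the ratios were 1.59 and 1.23. In aliquot 1 alone, with 1 to 5 UMIs each, Slc25a20 was at 0.849, Gcnt1 at 1.86, Nmrk1 at 1.3, Lpgat1 at 1.81, Cish at 1.81, Arrdc4 at 1.4 and Rnf219 at 1.5 times.

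The lowest ratios also included Scd2, a fatty acid desaturase, at 0.227 times (0.0979 to 0.449), and Erdr1 at 0.277 times (0.120 to 0.549). Serp1, of the endoplasmic reticulum, was at 0.295 times (0.135 to 0.563) and the transporters Slc22a3 and Slc18a2 at 0.341 and 0.387 times. Ywhag, Vezf1 and Surf4 followed at 0.362, 0.374 and 0.402 times. In aliquot 1 Cd34 was at 0.588, Serp1 at 0.675, Slc18a2 at 0.649, Scd2 at 0.146 and Surf4 at 0.962 times, while Erdr1, Slc22a3 and Ywhag had 0 UMIs there. Without the cell holding most of their UMIs, Plac8 was at 0.114 and Slc22a3 at 0.151 times. Because genes were ranked by ratio, these extremes overstate the difference by an amount that 1 pool cannot measure. In the LT-HSC-like class alone, 25 against 613 cells, Plac8 was at 0.941 times (0.111 to 3.6), Gcnt1 at 0.385 (0.00958 to 2.24) and Slc25a20 at 0.316 (0.00789 to 1.82).

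Of the 26 genes on the LT-HSC list, 21 were measured, 12 above 1 and 9 below. Their median log2 ratio was 0.14, at percentile 95.4 of random lists, inside the 95% range of -0.19 to 0.16. Ifitm1, an interferon-inducible membrane gene, was at 2.13 times (1.83 to 2.46) and Txnip, a regulator of redox state and glucose uptake, at 1.46 times (1.3 to 1.64). Sult1a1 and Gimap6 were at 1.94 (1.20 to 2.97) and 1.75 times (1.22 to 2.43), with 3.70 and 3.05 in aliquot 1. In the LT-HSC-like class they were at 0.91 (0.449 to 1.66) and 1.11 times (0.614 to 1.86). Hlf and Meis1 were near 1, at 0.978 and 0.95 times, and Pdzk1ip1 was at 0.585 times (0.319 to 0.986). The median depended on the cells compared. It was 0.38 against depth-matched other cells, 0.34 for cells with at least 2 reporter UMIs and -0.23 within the LT-HSC-like class. In aliquots 1 and 2 alone it was 0.42 and 0.20. Random lists were not drawn for these cell sets, so whether these medians lie inside their own ranges is not known. The LT-HSC-like class was named by raised markers, of which Mecom, Procr, Mllt3, Ly6a, Ltb, Sult1a1 and Gimap6 are on this list. Values within that class are therefore partly set by the clustering and do not locate the difference.

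The MPP and lymphoid list had 3 measured members and a median of -0.02: Cd34, Cd27 at 0.983 times (0.670 to 1.40) and Il12a at 2.97 times (1.39 to 5.63, 10 UMIs). Flt3, whose promoter drives the Cre, had 4 UMIs against 5.65 expected, too few for a direction. It was named after its value was seen.

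Immediate early genes, which are transcribed within minutes of stimulation, stood apart as a list. All 12 measured of 16 were above 1 in reporter cells, with a median log2 ratio of 0.72 against a random range of -0.21 to 0.31. Ier2 was at 1.46 times (1.16 to 1.82), Zfp36 at 1.49 (1.14 to 1.91), Dusp1 at 1.52 (1.15 to 1.97) and Jun at 1.25 (1.04 to 1.50), or 0.98 in aliquot 1. In aliquot 1 Ier2, Zfp36 and Dusp1 were at 2.27, 2.68 and 2.31 times. Fos, chosen after its value was seen, was at 2.35 times (1.85 to 2.94), with 4.25 in aliquot 1 and 1.94 in aliquot 2. Within the LT-HSC-like class the list had 8 measured members and a median of 0.20, with Fos at 0.314 times. The clustering itself placed cells rich in these genes in another cluster, so this does not locate the difference.

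The quiescence list, which shares Egr1, Klf6 and Btg2 with the immediate early list, had a median of 0.44 over 9 members (range of random lists -0.24 to 0.59). The interferon list had a median of 0.32 over 6 members (-0.33 to 0.42), with Bst2 at 1.63 times (1.1 to 2.34). S phase genes had a median of 0.01 over 15 members, with Mcm6 at 1.284 times (1.038 to 1.572), Mcm2 at 1.301, Dut at 0.9985 and Mcm7 at 0.777. G2 and M phase genes had a median of -0.07 over 13. Top2a was at 0.524 times (0.299 to 0.854), Hmgb2 at 0.646 (0.520 to 0.794), Tubb4b at 0.952 (0.704 to 1.26) and Mki67 at 1.275 (0.828 to 1.88). In aliquot 1 Top2a was at 1.37 times, Hmgb2 at 0.973, Tubb4b at 1.58, Mki67 at 0.714 and Mcm6 at 0.806. Both cell cycle medians lay inside the random ranges, -0.32 to 0.22 and -0.32 to 0.29.

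Heat shock (0.06), oxidative phosphorylation (-0.02), glycolysis and hypoxia (-0.13), ribosomal protein (-0.04), mitochondrially encoded (0.05), MHC (-0.07) and niche and adhesion genes (-0.01) had medians inside their random ranges. The sex-linked list had 2 measured members that went apart, with a median of -0.46: Ddx3y was at 1.83 times (1.05 to 2.96) and Eif2s3y at 0.290 times (0.0595 to 0.853, 3 UMIs). The sex of the mice is not given in the sources used here.

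**Figure D2:**
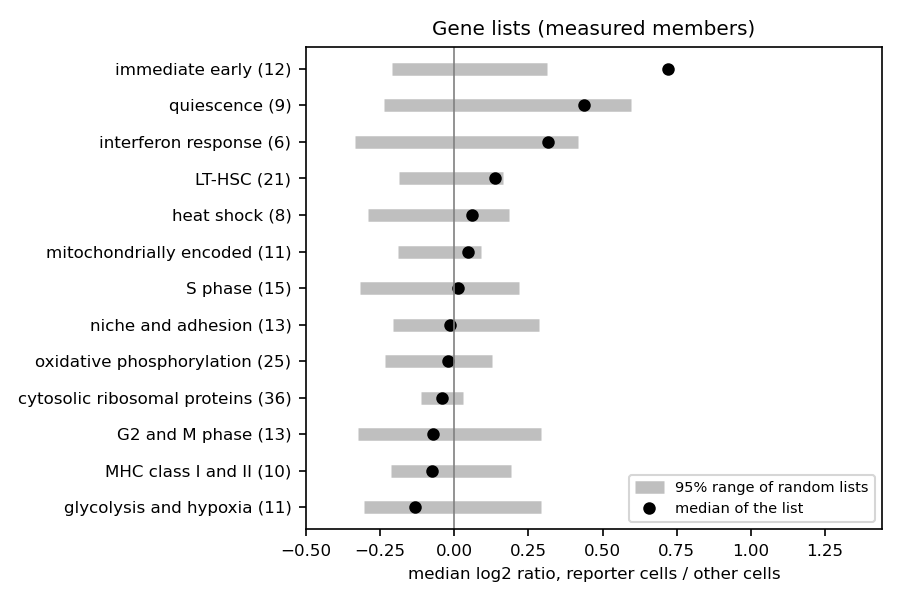
Median log2 ratio of reporter cells over other cells for 13 of the 15 gene lists, those with at least 5 measured members (number in brackets); the grey bar is the 95% range of 10000 random lists matched on expression. The immediate early list, at 0.72, lies above its range, and the other lists drawn lie inside theirs.

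Clustering of the 3402 cells gave 12 clusters, of which 1 was LT-HSC-like, 1 cycling and 2 held granulocyte markers. An LT-HSC-like cluster of 638 cells, 18.8% (17.5 to 20.1%), had 10 of 16 LT-HSC markers at least 2-fold higher, among them Procr, Fgd5, Slamf1 and Hoxb5, and was led by Neo1, Igf2, Gimap4, Efna1 and Gfi1, with the antigen presentation genes Cd74, H2-Aa and H2-Ab1 also raised. A cycling cluster of 476 cells, 14.0% (12.8 to 15.2%), had all 12 cycling markers and was led by Sapcd2, Car1, Nek2, Nusap1 and Sgol1, with 4 megakaryocyte markers and the erythroid markers Klf1, Car1 and Epor also raised. 8 clusters with 65.2% of cells met the rule for no marker list. The rule asks for markers 2-fold above all other cells, and those cells include the wild-type LT-HSCs of the pool. Unnamed cells may therefore be LT-HSCs too, and 18.8% is not the LT-HSC share of the pool. Procr was 1.7-fold higher in unnamed cluster 3 and Mecom 1.82-fold in unnamed cluster 8. Of these, cluster 6 (248 cells) was led by the immediate early genes Nr4a1, Klf2, Fos, Btg2 and Zfp36.

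The smallest clusters held granulocyte transcripts, although the wild-type sort excluded lineage-positive cells and the marrow was depleted with Gr1. Cluster 11 (16 cells) was neutrophil-like, led by Camp, Ltf, Ngp, S100a9 and Cd177. Cluster 10 (53 cells) was left without a type, since its leading genes Prss34 and Mcpt8 belong to basophils and mast cells while Ctsg, Elane and Mpo belong to neutrophil progenitors. Together they made 2.03% of cells (1.58 to 2.56%), 1.97% in aliquot 1 and 2.08% in aliquot 2. LT-HSC-like cells made 15.9% (14.1 to 17.8%) of aliquot 1 and 21.2% (19.4 to 23.2%) of aliquot 2, which differ in depth. These shares depend on the settings: LT-HSC-like cells made 29.2% at Leiden resolution 0.5, granulocyte-marker cells 0.976% with at most 10% mitochondrially encoded UMIs, and with no UMI minimum the LT-HSC-like, cycling and granulocyte shares were 27.9%, 9.06% and 7.79%. The genes of highest CPM in the pool were Eef1a1 at 21030, mt-Co2 at 11270 and mt-Atp6 at 10800.

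Of the 71 reporter cells, 25 were in the LT-HSC-like cluster, 35.2% (24.2 to 47.5%), against 613 of 3331 other cells, 18.4% (17.1 to 19.8%). Cluster 6, with immediate early genes, held 12 reporter cells, 16.9% (9.05 to 27.7%), against 7.08% of other cells. The cycling cluster held 12 reporter cells, 16.9% (9.05 to 27.7%), against 13.9% (12.8 to 15.2%). The 2 granulocyte-marker clusters held 0 reporter cells (up to 5.06%) against 2.07% (1.62 to 2.61%), so counting error covers that difference. Cluster 7, which is unnamed, also held 0 (up to 5.06%), against 6.87% of other cells (6.04 to 7.79%). Clustered without the 1013 genes over 1.5-fold apart between the cell sets, the LT-HSC-like shares were 40.8% (29.3 to 53.2%) and 26.2% (24.7 to 27.7%). In the first clustering, aliquot by aliquot, the shares were 21.7% (7.46 to 43.7%) against 15.8% in aliquot 1, with overlapping intervals, and 41.7% (27.6 to 56.8%) against 20.7% in aliquot 2. At Leiden resolution 0.5 the shares were 56.3% (44.0 to 68.1%) and 28.6%, and at 1.5 they were 22.5% (13.5 to 34.0%) and 16.6% (15.3 to 17.9%), with overlapping intervals. With no UMI minimum 70.2% of reporter cells and 27.9% of all cells were LT-HSC-like. Depth differs at that setting: 7372 of 10809 barcodes had under 500 UMIs, while 71 of the 85 with a reporter UMI were kept cells. Whether depth raised the share was not tested.

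**Figure D3:**
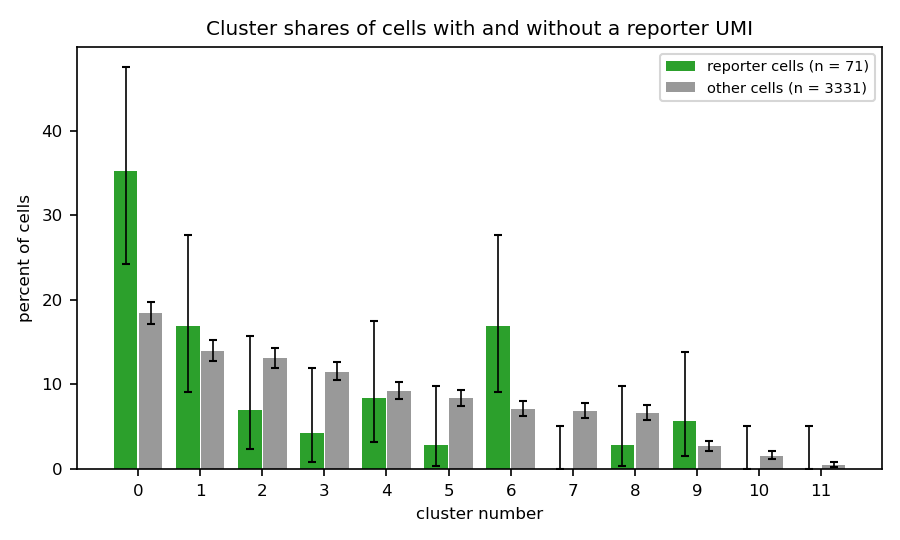
Percent of reporter cells (green, n = 71) and of other cells (grey, n = 3331) in each of the 12 clusters, with exact 95% intervals for counting error. Reporter cells have the higher share in cluster 0, LT-HSC-like, at 35.2% against 18.4%, and in cluster 6, led by immediate early genes, at 16.9% against 7.08%.

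Cells with a Mecom UMI after thinning had higher medians of LT-HSC genes and lower medians of cell cycle genes than cells in which none was found. After thinning to 500 UMIs, 237 cells had a Mecom UMI and 3165 did not, although before thinning 13 reporter and 494 other cells had one, so the second set also holds cells with a Mecom UMI. At the load of barcodes under 200 UMIs, free RNA would give 39.2 Mecom UMIs (12.7 to 91.4) in kept cells of aliquot 1, against 253 found, and 21.5 (16.9 to 27.0) in aliquot 2, against 503. Per UMI, Mecom was no lower in those barcodes than in kept cells, at 165 against 154 CPM in aliquot 1 and 141 against 125 in aliquot 2. If free RNA rose with the depth of a cell, the load would therefore set no limit on it. The LT-HSC list had a median log2 ratio of 0.30, above the random range of -0.16 to 0.16, with 17 of 20 members above 1. Hlf was at 1.35 times (1.12 to 1.61), Ifitm1 at 1.52 (1.26 to 1.81) and Sult1a1 at 1.77 (1.06 to 2.80). S phase genes had a median of -0.38 (random range -0.28 to 0.23; 9 of 12 below 1) and G2 and M phase genes -0.63 (-0.37 to 0.30; 4 of 6 below 1), or -0.26 in aliquot 2 alone with 2 members. At a minimum of 5 UMIs per gene, aliquots 1 and 2 alone gave medians of 0.16 and 0.43 for LT-HSC, -0.13 and -0.62 for S phase and -0.46 and -0.74 for G2 and M phase genes, so the S phase difference came mainly from aliquot 2. The niche and adhesion list had a median of 0.24 (-0.22 to 0.23; 10 of 12 above 1). These values come from 1 random thinning. Over 20 other draws the medians ran from 0.16 to 0.58 for LT-HSC, -0.82 to -0.26 for S phase, -1.02 to -0.30 for G2 and M phase and -0.09 to 0.20 for niche genes, so the last has no set direction. Of single granulocyte genes, Camp had 0 UMIs against 26.4 expected in cells with Mecom, and Lyz2 was at 0.492 times (0.337 to 0.696). Before thinning, 1500 of the 1521 Camp UMIs in cells without a reporter UMI came from the 16 cells of cluster 11. The 0 therefore rests on few cells, and no direction follows from it. Itga2b, of megakaryocytes and early progenitors, was at 0.277 times (0.0748 to 0.722). Camp and Lyz2 were chosen after their values were seen, and so was Itga2b. Without the granulocyte clusters the draws gave 0.13 to 0.56 for LT-HSC and -0.84 to -0.26 for S phase genes. Mcm6, of the replicative helicase, was at 0.611 times (0.425 to 0.854) and Hmgb2 at 0.593 (0.454 to 0.762). Cd34 was at 0.589 times (0.351 to 0.931), and Kit at 1.21 (0.980 to 1.49), where in reporter cells Kit was at 0.575.

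Mecom was found in 6 of 71 reporter cells after thinning, 8.45% (3.16 to 17.5%), and in 231 of 3331 other cells, 6.93% (6.10 to 7.85%). Without thinning the shares were 18.3% and 14.8%. The intervals overlap, so a difference in Mecom detection was not detectable at this depth.

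The 2 aliquots gave like profiles. Across 5993 genes with at least 50 UMIs in each, Pearson's r of log2 CPM was 0.966 and Spearman's rho 0.944, values across genes, which are not independent replicates. 89 genes were over 2-fold apart. Those furthest apart, chosen after their values were seen, were lower in aliquot 1 and were ribosomal protein genes or their pseudogene copies, such as Rpl36 at 30.5 against 214 CPM and Rpl10a at 396 against 1303 CPM, where reads shared between copies make the values uncertain.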

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

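All tests in this part were chosen after the result was seen.

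Barcodes outside the kept cells held 14 reporter UMIs in 14 barcodes, a signal in data that the comparisons do not use and above the 3 counts that a count of 0 allows. They made 16.3 CPM there, against 21.9 CPM in kept cells. Barcodes under 200 UMIs in aliquot 2 held 11 of them, 20.9 CPM over 6291 barcodes, and those of aliquot 1 held 0 over 201 barcodes.

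Reporter UMIs in kept cells could be RNA free in the suspension. As the whole source this is argued against by their clumping: 30 cells had 2 or more reporter UMIs, while 10000 draws that spread the same 124 UMIs over cells by depth gave a median of 3 and at most 9. For cells with 1 reporter UMI, the 20 genes furthest from 1 in cells with 2 or more, against 1666 of the other cells, were read in the 41 cells with 1 against the remaining 1665, with a Mantel-Haenszel ratio over aliquots. Their median log2 ratio in the same direction was 0.367, above the random range of -0.23 to 0.24, with 15 of 20 in the same direction, which argues against free RNA as the source of all 1-UMI cells. At the load of barcodes under 200 UMIs, kept cells of aliquot 2 would hold 3.2 free reporter UMIs (1.6 to 5.72), against 87 found. In aliquot 1 that load allows up to 28.9, against 37 found. How many of the 41 hold free RNA stays open, more so in aliquot 1, and no biological explanation was tested.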

How the results depend on the processing

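The alternatives named here as removing the top cell per gene or the cycling and granulocyte classes were chosen after seeing the data. Of the medians outside their random range, only that of niche and adhesion genes in the Mecom split changed sign. It ran from -0.09 to 0.20 over other draws of the thinning. Of the values that answer a comparison, 192 moved by less than the spread between aliquots, or for counts and r by less than their limits, and 43 by more. The single-aliquot values mostly set that spread and are also counted, so the tally does not measure how stable the results are. The cause of the changes below was not tested.

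Leaving out 1 aliquot gave 23 to 48 reporter cells and list medians of 0.20 to 0.42 for LT-HSC, 0.21 to 0.53 for S phase, -0.22 to 0.31 for G2 and M phase, 0.52 to 1.42 for immediate early and 0.10 to 2.10 for quiescence genes. In aliquot 1 these rest on 2 S phase, 2 G2 and M phase and 1 quiescence gene. For MPP genes only aliquot 2 gave a median, -1.08, from 2 genes. At a minimum of 5 UMIs, aliquots 1 and 2 gave -0.13 and 0.21 for S phase, 0.83 and -0.28 for G2 and M phase and -0.36 and 0.14 for MPP genes, so these have no set direction. In the Mecom split the ranges were -0.55 to 0.16 for MPP and -0.52 to -0.26 for G2 and M phase genes. From aliquot 1 alone to aliquot 2 alone, Slc25a20 went from 0.849 to 3.91 times, H2-Q4 from 0.685 to 1.52, Mcm6 from 0.806 to 1.45, Jun from 0.98 to 1.36, mt-Co2 from 1.11 to 0.919, Hspa8 from 1.21 to 0.741 and Top2a from 1.37 to 0.332.

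Requiring 2 reporter UMIs left 30 cells, with medians of 0.34 for LT-HSC, -0.81 for MPP and 0.38 for S phase genes and Egr1 at 0.988 times. In the LT-HSC-like class alone the LT-HSC median was -0.23 and the S phase median -0.27. Gcnt1 was there at 0.385, Slc25a20 at 0.316, Sult1a1 at 0.910, Zfp36 at 0.769, Mcm6 at 0.831 and Jun at 0.947 times. That class was named by markers on the LT-HSC list, so its LT-HSC values do not locate a difference. Depth-matched other cells gave an LT-HSC median of 0.38. Without the cycling and granulocyte classes the MPP median was -1.02 and Mcm6 was at 0.865 times. Without the cell holding most UMIs of each gene, which lowers every ratio by construction, the medians were -0.051 for LT-HSC, -0.22 for S phase and -0.52 for G2 and M phase genes. A gene minimum of 30 gave -0.90 for MPP, 0.36 for S phase and -0.63 for G2 and M phase genes, and -0.31 for the last in the Mecom split. There it was -0.37 without thinning, -0.81 thinned to 1000 UMIs and -0.93 with no mitochondrial limit.

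With no UMI minimum the MPP median was 0.50, the LT-HSC-like, cycling and granulocyte classes made 27.9%, 9.06% and 7.79% of cells, and 70.2% of reporter cells were LT-HSC-like. A minimum of 1000 UMIs gave 18.4% cycling and 2.34% granulocyte cells and r = 0.953, and a gene minimum of 10 gave r = 0.964. No mitochondrial limit gave 9.72% cycling and a limit of 10% gave 0.976% granulocyte cells. Leiden resolution 0.5 gave 29.2% LT-HSC-like and 15.5% cycling cells and 56.3% of reporter cells LT-HSC-like, and resolution 1.5 gave 11.8% cycling. Without cell cycle genes in the clustering 19.5% were cycling. Depth limits the reporter comparison: 71 cells and 137016 UMIs left 3 MPP genes measurable. No paired analysis was possible because there is 1 group.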

Other observations

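The tests of explanations in this part, on granulocyte and cycling cells, handling and shared barcode names, were chosen after the result was seen.

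Among summed marker lists, granulocyte markers were at 0.213 times in reporter cells (0.169 to 0.265; 81 UMIs against 380 expected), but at 1.17 (0.927 to 1.46) without the 69 cells of the granulocyte-marker clusters, so that difference lies in those cells. Mast cell and basophil markers were at 0.493 times (0.373 to 0.640) and erythroid markers at 0.689 (0.587 to 0.804), or 0.573 and 0.671 without those cells. Kit, a member of the mast cell and basophil list, gave 54 of its 57 UMIs in reporter cells and 94.0 of the 116 expected. That list therefore largely repeats the Kit ratio. Car2, of the erythroid list, was at 1591 CPM in thinned cells without a Mecom UMI. The whole erythroid list made 1738 CPM in cells without a reporter UMI, another set of cells and not thinned. Car2 is thus likely a large part of that list. The ratio of Car2 in reporter cells is not given here, so the source of the erythroid difference stays open. Megakaryocyte markers were at 1.25 times (1.05 to 1.47; 147 UMIs against 118 expected), most of it from Pf4, platelet factor 4, with 42 UMIs against 15.5 expected. Without the cycling and granulocyte classes Pf4 was at 1.46 times (0.724 to 2.66), an interval that includes 1. LT-HSC markers were at 1.12 times (1.02 to 1.22), or 1.09 (0.998 to 1.19) without the granulocyte-marker clusters. MPP or lymphoid markers were at 0.747 (0.583 to 0.943; 72 UMIs against 96.4 expected). Cd34 gave 11 of these UMIs against 37.8 expected, and Cd27 gave 32 against 32.6, so that difference lies in Cd34 and not in the list as a whole. S100a8, a neutrophil gene, had 0 UMIs in reporter cells against 59.3 expected. S100a9 had 2 UMIs against 85.4 expected, a ratio of 0.0234 (0.00284 to 0.0847). In other cells, 2253 of 2395 S100a8 UMIs and 3350 of 3446 S100a9 UMIs came from the 16 cells of cluster 11, so the contrast rests on few cells and no limit on the fold follows from it. B cell, T or NK cell, monocyte, endothelial, stromal and cycling markers were at 1.12, 0.710, 0.970, 1.35, 1.28 and 0.935 times, each with an interval that includes 1. Pf4, S100a8 and S100a9 were chosen after their values were seen.

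The higher immediate early transcripts of reporter cells could come from granulocyte and cycling cells among the other cells. Without those classes in both sets the list's median log2 ratio was 0.841, against 0.721 with all cells. It lay above the random range of -0.173 to 0.387 in the same cells, so the difference was also present outside those classes. The cycling class made 16.9% of reporter and 13.9% of other cells, and the granulocyte class 0% and 2.07%. With shares this low and alike, removing them could change the median little, so the test says no more about them as a cause. Handling or sorting of the 2 sources could also raise these transcripts, whose medians were 1.42 and 0.58 in aliquots 1 and 2 at a minimum of 5 UMIs per gene, and 0.52 in aliquot 2 at 10. This cannot be told apart from genotype or cell state, because sort, mouse line and cell source go together and the source of each cell is not recorded. The reporter genotype stays among the open explanations, as untested.

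The 2 aliquots shared 461 barcode names, where independent draws from 147448 names give 126 and at most 148 at the upper 95% limit, so chance reuse of barcodes is argued against. In aliquot 2, 10.6% of the 1860 barcodes with at least 500 UMIs were shared and 3.88% of the shallower ones. Of 212 same-named pairs with at least 200 UMIs on both sides, 69.8% (63.1 to 75.9%) were nearer in profile than a pair matched on depth, consistent with molecules of one library counted in the other as a candidate source. 9 kept reporter cells had a shared name. Uneven abundance of barcodes was not tested and stays open, and no biological explanation was tested.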
